A study of Mus musculus with 4 samples.

How the data were processed

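Total RNA was sequenced from splenic B cells of adult male mice of the cross B6CASTF1/J, which have a C57BL/6 mother and a CAST/EiJ father, at 62 days of age. The sample description names CD19, a surface protein of B cells. The 4 libraries form 1 group and are numbered as biological replicates 1 to 4 in the labels. They have separate biosample records but 1 donor record, and the labels do not say whether they came from separate animals, so p-values measure the spread between these samples, which may be technical. Each library was made from 300 ng of RNA with ERCC spike-ins, per the labels, and the linked library protocol is for a directional kit. The strand setting of the quantification is not given in the sources used here.

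Of the 16 files, 12 hold measurements. For each library the authors deposited a gene table and a transcript table with expected counts and TPM (length-corrected transcript abundance, which divides by length and scales every library to the same total), derived from alignments to the transcriptome, per the deposited text descriptions. They also deposited a transcript table with estimated counts and TPM derived directly from the reads, called read-based below. The deposited text descriptions name the mm10 build and the M21 gene annotation. The names and versions of the quantification programs are not given in the sources used here. TPM was scaled over all targets, including spike-ins and small structural RNAs, so the TPM of a protein-coding gene also depends on how much of those RNAs a library holds.

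All coordinates and gene names were taken from the M21 annotation on mm10. Of the 382 symbols in the fixed gene lists, 380 were in it. Where a symbol had several gene identifiers, the most abundant was used. Rows of spike-ins and of tRNAs were left out of gene counts, library sizes and tests. Gene totals were 17103018, 16303059, 16153620 and 16046632 expected counts in replicates 1 to 4. A count of 0 allows up to 3 counts, which is 0.175 to 0.187 CPM (counts scaled to the library size), and this limit covers counting error only because the reads carry no molecular identifiers in the tables used.

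Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). The design had an intercept only, with TMM scaling and the default expression filter, which left 12943 genes. The biological coefficient of variation is the square root of the common dispersion. A gene was called hypervariable when its quasi-dispersion lay above the abundance trend by an upper-tail F test with Benjamini-Hochberg adjustment at 0.05. This procedure was tested on simulated data for the 4 libraries over 12943 genes with a coefficient of 5%, of which 200 were made more variable. The common dispersion of the unchanged genes alone, without TMM scaling, gave 5.08%. Over all simulated genes, the procedure recovered 69% of those at a coefficient of 50% and 88% of those at 100%, with 0 false calls. All unchanged genes were simulated at the same coefficient, and no reads were divided between near-identical genes. The 0 false calls therefore do not cover calls that arise from such reads or from unequal coefficients.

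Gene lists were compared within each library by the median of log2(TPM+1), and gene pairs by the log2 ratio of TPM with a pseudocount of 0.1. Both used an exact two-sided sign-flip permutation test over the 4 libraries, adjusted over the family of 33 lists or 26 pairs. This test has 16 sign patterns and cannot give a p below 0.125, so no within-library comparison could reach 0.05. Each list's median was also placed among 10000 random lists of protein-coding genes of the same size. A gene counted as present at a mean TPM of at least 1. Shares and levels are means ± SD of 4 libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and figures were drawn with matplotlib 3.10.9.

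The named genes followed a rule fixed before the data were examined, as were the 34 lists, the pairs and the alternatives listed below. It takes up to 4 members of each list with the highest mean TPM, and every member of a list of another cell type at a mean TPM of 10 or more. It also takes the 20 most abundant protein-coding genes outside the mitochondrial genome, the 20 hypervariable genes with the smallest adjusted p, every gene of the pairs and of the immunoglobulin lists, and the sex-linked genes. The enrichment of the lists among hypervariable genes (one-sided Fisher's exact test) and the search for genes that share sequence were added after seeing the data. In that search the most abundant transcript of a gene was compared with all annotated transcripts, and a gene counted as sharing sequence when another gene covered at least 50% of it at 97% identity. The alternatives were other scalings, filters, pseudocounts, units and summaries, DESeq2 1.42.0, the read-based quantification, and leaving out each replicate in turn. No group contrast was made because there is 1 group.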

Results

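Total RNA-seq libraries from splenic B cells of male B6CASTF1/J mice were measured in 4 replicates of 1 group. They held 17103018, 16303059, 16153620 and 16046632 expected counts on annotated genes in replicates 1 to 4. Since the series holds a single group, the design implies a description of B cell expression, of its spread between replicates, and of comparisons between genes within a library. Of 55536 annotated genes, 12439 were present at a mean TPM of at least 1, among them 9998 of the 22028 protein-coding genes.

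The B cell identity genes were abundant in every library. All 16 members of the list were present at a mean TPM of at least 10, with a median of 238 TPM, above 100% of the random lists of protein-coding genes. Cd37, a tetraspanin of lymphocytes, stood at 581 ± 34.4 TPM (SD, n = 4). Cd79a and Cd79b, the signalling chains of the B cell receptor, stood at 566 ± 22.0 and 435 ± 36.5 TPM (SD, n = 4). Cd19 (ENSMUSG00000030724.7, chromosome 7, 126408450 to 126414889, mm10), the coreceptor named in the sample description, was measured at 385 ± 14.8 TPM. Ms4a1, which encodes CD20, was at 229 ± 10.4 TPM and Pax5, the transcription factor that maintains B cell identity, at 359 ± 28.5 TPM (SD, n = 4).

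The other B cell lists were present nearly in full. All 18 genes of B cell receptor signalling were present, led after the receptor chains and Cd19 by the kinase Syk at 305 ± 11.2 TPM. All 13 coreceptor and inhibitory genes were present, with Cd22 at 374 ± 42.4, Inpp5d at 239 ± 13.8, Ptpn6 at 185 ± 9.67 and Cd72 at 158 ± 18.4 TPM. All 19 B cell transcription factors were present, and Klf2, a factor of quiescent and recirculating lymphocytes, was the most abundant at 1262 ± 156 TPM. Of the 14 genes of MHC class II presentation, 13 were present. The invariant chain gene Cd74 (chromosome 18, 60803848 to 60812652) was the most abundant protein-coding gene outside the mitochondrial genome at 5949 ± 308 TPM. H2-Ab1, H2-Aa and H2-Eb1, which encode class II chains, followed within this list at 1946 ± 112, 1699 ± 61.4 and 1280 ± 72.7 TPM, and H2-Ab1 and H2-Aa changed order when length was not corrected for.

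The 20 most abundant protein-coding genes were otherwise led by translation and cytoskeleton genes. Rps27 stood at 3362 ± 121, Eef1a1 at 2854 ± 77.6, Actb at 2711 ± 148 and Tpt1 at 1845 ± 89.4 TPM (SD, n = 4). The ribosomal protein genes Rplp1, Rps29, Rpl13a, Rps24, Rpl18a, Rpl41, Fau and Rps28 lay between 1696 and 1131 TPM. H3f3b, Ddx5 and Tmsb4x were at 1146 ± 72.9, 1118 ± 45.4 and 1104 ± 62.8 TPM.

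Lists of receptors were split among their members. Of the 8 TNF family genes, 6 were present, led by Ltb at 201.02 ± 9.94 TPM. Tnfrsf13c, the BAFF receptor, was at 101 ± 7.25 TPM and Tnfrsf13b, which encodes TACI, at 55.4 ± 5.06 TPM, while Tnfrsf17, the plasma cell receptor BCMA, was at 0.10 ± 0.146 TPM. Of the 14 homing receptors in the annotation, 13 were present. Ccr7, a receptor for T zone chemokines, stood at 309 ± 15.3 TPM, above the follicle receptor Cxcr5 at 89.0 ± 5.97 TPM, a 3.47-fold difference with the same direction in 4 of 4 libraries. Sell was at 190 ± 6.6, Cxcr4 at 175 ± 20.8 and S1pr1 at 108 ± 5.50 TPM, and the order of Cxcr4 and S1pr1 turned when CPM replaced TPM. Of the 15 Toll-like receptor and innate genes, 13 were present, led by Unc93b1 at 187 ± 8.24 and Cd180 at 184 ± 9.61 TPM. The DNA sensor Tlr9 was at 50.9 ± 3.86 TPM, 3.90 times Tlr7 at 13.0 ± 1.15 TPM and 7.99 times Tlr3 at 6.30 ± 0.729 TPM, on the scale of TPM + 0.1.

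Markers of follicular B cells were the most abundant of the subset lists. All 9 were present with a median of 229 TPM, and the list's median log2(TPM+1) lay 0.06 below that of the identity list, higher in the identity list in 3 of 4 libraries; the difference of identity minus follicular list turned to -0.32 with the read-based quantification and to -0.12 with list means. Fcer2a, which encodes CD23, was at 229 ± 25.8 TPM, Ighd at 642 ± 48.4 TPM and Cr2 at 298 ± 18.3 TPM. Of 12 marginal zone markers 11 were present, with a median of 21.2 TPM: Cr2, Plac8 at 134 ± 6.25, Dtx1 at 82.8 ± 4.61, Mzb1 at 79.5 ± 4.96 and Cd1d1 at 33.8 ± 2.73 TPM. Fcer2a exceeded Cd1d1 by 6.72 times in TPM and by 12.2 times in CPM. B1 cell markers had a median of 1.97 TPM with 7 of 11 present, led by Ahnak at 48.8 ± 4.17 and Bhlhe41 at 10.6 ± 0.928 TPM. Of 10 transitional markers 5 were present, and Cd24a at 213 ± 18.3 and Vpreb3 at 36.0 ± 1.85 TPM were the only ones at 10 TPM or more.

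Germinal centre genes were mostly low, and plasma cell genes were split among their members. Of 11 germinal centre genes 5 were present, with Neil1 at 24.8 ± 1.91 and Bcl6 at 24.7 ± 2.72 TPM above 10. Of 12 plasma cell genes 11 were present, 6 of them at 10 TPM or more, with a median of 14.4 TPM above 97.9% of the random lists, led by Irf4 at 197 ± 16.3, Mzb1, Jchain at 46.2 ± 9.37 and Xbp1 at 37.5 ± 2.35 TPM. Prdm1, the driver of plasma cell differentiation, was at 2.22 ± 0.226 TPM, below the factors that oppose it. Pax5 exceeded it by 155 times, Bach2 at 154 ± 14.3 TPM by 66.5 times and Bcl6 by 10.7 times, in 4 of 4 libraries each.

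**Figure D1:**
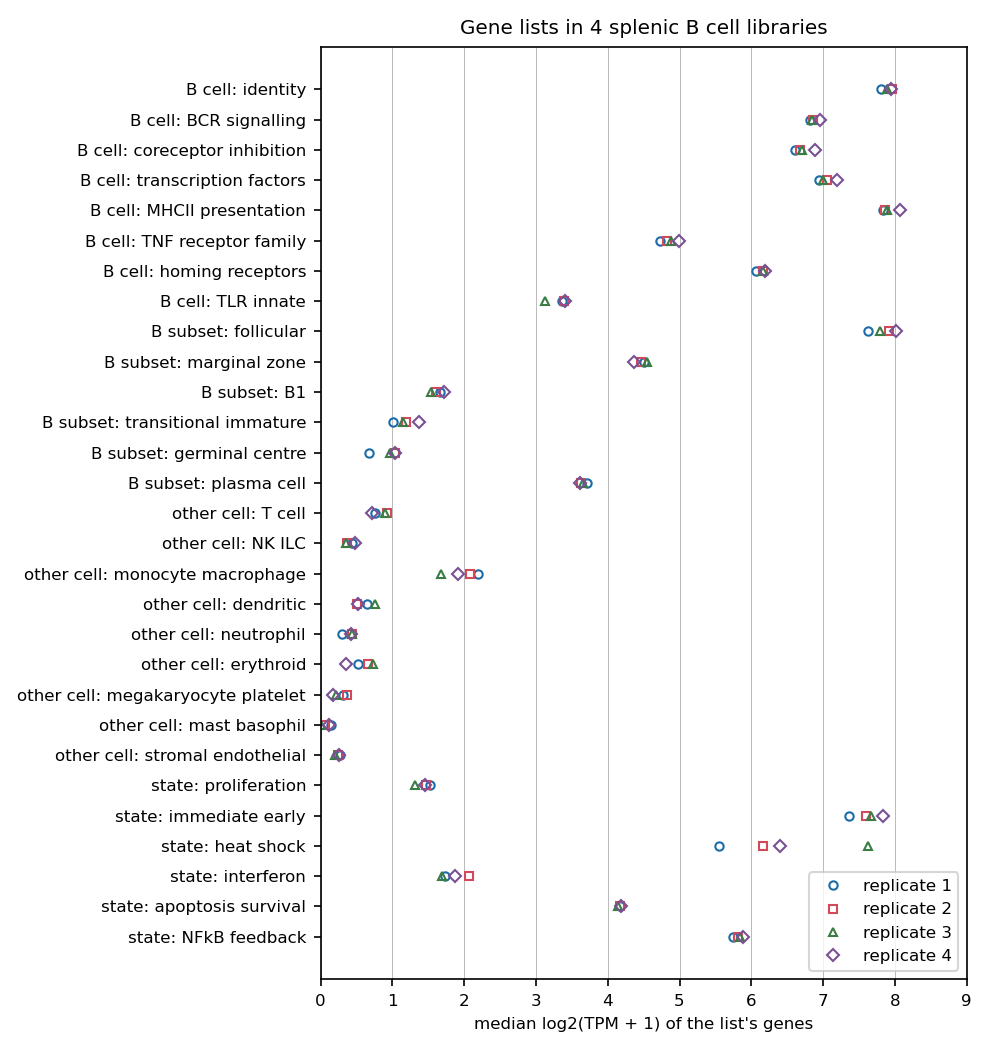
The horizontal axis gives the median log2(TPM + 1) of the genes of each list and each row is a list of B cell, B cell subset, other cell type or cell state genes. Each symbol is 1 of the 4 libraries, and the lists of other cell types reach at most 2.20 in any library while the identity list lies at 7.81 or above.

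Markers of other spleen cell types were low next to the identity genes. Their lists lay above 24.3% (mast cells and basophils) to 84.3% (monocytes and macrophages) of the random lists. Random lists were drawn from all 22028 protein-coding genes, of which 9998 were present. The 9 lists had medians between 0.095 TPM (mast cells and basophils) and 3.08 TPM (monocytes and macrophages), and the identity list exceeded each of them by 5.93 to 7.82 on the log2(TPM+1) scale, in 4 of 4 libraries (exact sign-flip permutation p = 0.125, adjusted p = 0.133 over the family). This range was 6.88 to 9.14 with CPM, 6.31 to 10.6 with log2(TPM+0.1) and 4.60 to 7.65 over members with a mean TPM of at least 0.1. Of the T cell genes 7 of 16 were present, led by Lck at 8.09 ± 1.81, Trbc2 at 1.46 ± 0.565, Lat at 1.40 ± 0.255 and Tcf7 at 1.34 ± 0.189 TPM, and Cd19 exceeded Cd3e by 286 times (593 in CPM, and 172 with a pseudocount of 1). Of the monocyte and macrophage genes 12 of 18 were present, led by Hmox1 at 6.27 ± 0.906 and Cd68 at 4.80 ± 0.261 TPM, and Ms4a1 exceeded Lyz2 by 74.1 times (179 in CPM). NK and innate lymphoid genes were present in 2 of 11 cases, led by the cytotoxic gene Prf1 at 5.81 ± 0.152 TPM. Neutrophil genes were present in 2 of 13 cases (S100a9 at 3.60 ± 0.495 and S100a8 at 2.79 ± 0.841 TPM), platelet genes in 1 of 11 (Itga2b at 2.75 ± 0.538 TPM), and mast cell and basophil genes in 0 of 8. Among dendritic cell genes 3 of 12 were present: Ly6d at 218 ± 10.04, Cst3 at 53.5 ± 4.18 and Bst2 at 9.44 ± 2.59 TPM. The median of this list was 0.529 TPM, and the libraries do not show which cells expressed these 3 genes. Pecam1, which is also in the list of B cell inhibitory receptors, was the 1 present gene of the 12 stromal and endothelial genes at 81.5 ± 5.06 TPM. Erythroid genes were present in 5 of 11 cases, with the globin genes Hba-a1 at 29.3 ± 8.74, Hbb-bs at 25.4 ± 10.3 and Hba-a2 at 18.6 ± 11.6 TPM.

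The male label was checked with sex-linked genes. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d stood at 49.8 ± 3.32, 45.8 ± 2.38, 17.5 ± 1.18 and 14.6 ± 1.28 TPM. Xist, which is expressed from the inactive X chromosome of females, was at 0.0475 ± 0.0150 TPM (SD, n = 4).

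Immunoglobulin transcripts were mainly IgM and IgD. Ighm (chromosome 12, 113418558 to 113422730) made up 76.8% ± 0.524 of the heavy-chain constant-region TPM and Ighd 21.9% ± 0.803 (SD, n = 4), so Ighm exceeded Ighd by 3.51 times. Ighm stood at 2253 ± 134 TPM. The switched isotypes together made up 1.28% ± 0.318, of which Ighg3 had 0.833% ± 0.178, Ighg2c 0.176% ± 0.164 (0.0936% without replicate 3), Ighg2b 0.160% ± 0.0488, Igha 0.0722% ± 0.0251, Ighg1 0.0362% ± 0.0149 and Ighe 0.00121% ± 0.00151 (0.000573% without replicate 3). Of the light chains, Igkc (chromosome 6, 70726435 to 70726966) stood at 2498 ± 158 TPM. The lambda genes Iglc2, Iglc1, Iglc3 and Iglc4 on chromosome 16 were at 799 ± 40.9, 769 ± 79.1, 179 ± 15.4 and 2.07 ± 0.418 TPM. Lambda made up 41.2% ± 0.324 of the light-chain constant-region TPM, and 8.31% ± 0.504 of the counts on light-chain variable genes.

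Transcripts of Ighm that end in the membrane exons (113418558 to 113422730) carried 1479 ± 121 TPM and the shorter form with the secretory end (113420741 to 113422730) 774 ± 47.3 TPM. The membrane form thus made up 65.6% ± 2.28 of Ighm. The form of Ighd that reaches position 113406604 made up 92.2% ± 1.16 of Ighd. Of Ptprc, which encodes CD45, the transcript with all 3 alternative exons (Ptprc-207) made up 96.3% ± 1.62 of the 3 full-length coding transcripts and 41.3% ± 1.04 of all Ptprc transcripts, the rest being annotated as retained introns or the forms that lack those exons. These shares rest on how reads common to both forms were divided.

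Gene pairs set related B cell factors against each other, and each named pair below kept its direction in 4 of 4 libraries. Spib exceeded its relative Spi1 by 4.22 times (148 ± 9.03 and 35.3 ± 4.50 TPM), Foxp1 exceeded Foxo1 by 9.10 times (390 ± 25.8 and 42.7 ± 1.78 TPM), and Ikzf3 exceeded Ikzf1 by 1.81 times (211 ± 21.1 and 116 ± 8.78 TPM). Of the NF-kB genes, Rel exceeded Rela by 2.02 times and Nfkb1 exceeded Nfkb2 by 1.19 times. The inhibitory Fc receptor Fcgr2b was at 73.3 ± 2.27 TPM and Fcgr3 at 0.748 ± 0.283 TPM. The costimulatory gene Cd86 was at 58.7 ± 3.10 TPM and Cd80 at 0.623 ± 0.176 TPM. The survival gene Mcl1 at 134 ± 17.0 TPM exceeded Bcl2 at 25.1 ± 1.27 TPM by 5.29 times, and Bcl2 exceeded Bcl2l1 at 2.79 ± 1.16 TPM by 9.27 times. Cdkn1b, a cell cycle inhibitor, was 21.7 times Mki67 at 1.83 ± 0.487 TPM. Tnfrsf13c exceeded Tnfrsf13b by 1.82 times, Igkc exceeded the sum of Iglc1, Iglc2 and Iglc3 by 1.43 times, and Cd79a exceeded Cd79b by 1.30 times. Folds between genes of unequal length depend on the unit: with CPM, which does not correct for length, the same comparisons gave 1.96 times for Foxp1 and Foxo1, 6.88 for Rel and Rela, 2.87 for Mcl1 and Bcl2, 30.7 for Bcl2 and Bcl2l1, and 7.39 for Cdkn1b and Mki67.

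Cell state genes differed widely in level. Immediate-early genes, which respond within minutes to activation or handling of cells, were present in 18 of 19 cases with a median of 205 TPM, above 100% of the random lists. Fosb was at 986 ± 193, Jund at 869 ± 93.4, Fos at 701 ± 170 and Junb at 590 ± 75.3 TPM (SD, n = 4). All 11 heat-shock genes were present with a median of 106 TPM, led by Hspa8 at 512 ± 33.4, Hsp90ab1 at 376 ± 30.4, Hsp90aa1 at 210 ± 20.1 and Dnaja1 at 158 ± 27.9 TPM. All 11 genes of NF-kB feedback were present, led by Tnfaip3 at 279 ± 33.0 TPM, and all 13 genes of apoptosis and survival, led by Mcl1 and Bcl2l11 at 88.9 ± 5.12 TPM. Proliferation genes had a median of 1.66 TPM with 12 of 15 present, led by Pcna at 86.3 ± 6.16 and Mcm2 at 19.8 ± 0.947 TPM. Interferon-response genes had a median of 2.40 TPM with 11 of 15 present, led by Stat1 at 46.2 ± 4.94 and Irf7 at 12.5 ± 1.73 TPM.

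The replicates differed by a biological coefficient of variation of 6.56%, and 64 of 12943 tested genes were hypervariable at an adjusted p below 0.05 in edgeR (560 at an unadjusted p below 0.05). Of these, 17 are in the fixed lists: 5 of 11 heat-shock genes (9 adjusted over the list alone), 7 of 18 tested immediate-early genes (13 adjusted over the list alone), 3 of 5 tested erythroid genes (4 adjusted over the list alone), Ighg2c and Jchain. The one-sided Fisher's exact test, chosen after seeing the data, gave an adjusted p of 5.2e-11 for the immediate-early, 1.9e-08 for the heat-shock and 1.3e-05 for the erythroid list, and above 0.28 for the others. It treats genes as independent, which genes of one response are not.

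The heat-shock genes Hspa1b (chromosome 17, 34956436 to 34959238) and Hspa1a (34969190 to 34972156) spanned 4.79 and 5.29 times between libraries, with 628 and 357 CPM in replicate 3 and at most 220 and 135 in the others (edgeR adjusted p = 1.7e-06 for both). These adjacent genes share near-identical sequence, so the division of reads between them is uncertain. Hsph1 at 399 CPM in replicate 3 (adjusted p = 0.00071 in edgeR), Dnajb1 at 205 and Dnaja1 at 382 were also highest there. Egr1 reached 567 CPM in replicate 4 and was lowest in replicate 1 at 311 (edgeR adjusted p = 0.0013), as were Fos (1603 and 987), Fosb (4286 and 2966), Jun, Egr2, Dusp1 and Ier2, and all 7 were second highest in replicate 3 under TMM scaling. Replicate 1 also held the largest and replicate 4 the smallest share of counts on snRNA genes, 0.681% and 0.480%. Dnajb1, Jun, Egr2, Dusp1 and Ier2 are named as the remaining called members, chosen after their values were seen. Hba-a1, Hba-a2 and Hbb-bs were highest in replicate 1 or 2, Ighg2c stood at 13.0 CPM in replicate 3 and at most 2.99 in the others, and Jchain was lowest in replicate 2 at 43.6. The number of hypervariable genes was 41 without replicate 1, 37 without replicate 2, 244 with no filter on low counts and 0 with a robust prior (437 at an unadjusted p below 0.05). Without replicate 3, 2 of the 5 heat-shock calls were left. Of the 7 immediate-early calls, 2 were left without replicate 1 and 4 without replicate 2, 3 or 4, and of the 3 erythroid calls 1 without replicate 1 or 2 and 0 without replicate 4. With a mean count of at least 50 required, 13 of the 17 listed calls were left, 5 of them immediate-early and 1 erythroid. The call of Ighg2c was lost without replicate 3 (adjusted p = 0.998 in edgeR) and that of Jchain without replicate 2 (0.989) or 3 (0.0556). Spike-in scaling moved all genes alike, by 0.23, -0.05, -0.21 and 0.02 on the log2 scale in replicates 1 to 4. Of the 17 listed calls, 6 were then left, as the coefficient of variation over all genes rose from 6.56% to 15.0%. Those left were 2 of 5 heat-shock calls, all 3 erythroid calls and that of Ighg2c. Of the immediate-early calls 0 of 7 were left, and the call of Jchain was lost. The 5 heat-shock genes stayed highest in replicate 3, with a median log2 ratio to the mean of the others of 0.55 ± 0.650 (SD over genes) against 0.82 ± 0.642 with TMM. The 7 immediate-early genes stayed highest in replicate 4, with 0.43 ± 0.145 against 0.39 ± 0.142, while the shift changed their order among replicates 1 to 3.

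**Figure D2:**
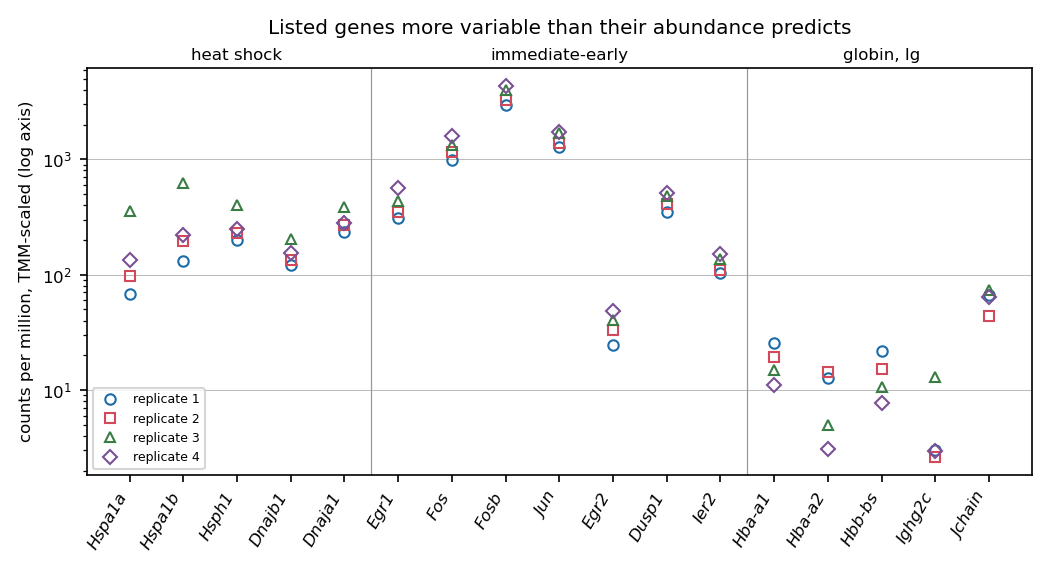
The vertical axis gives TMM-scaled CPM on a log axis for the 17 listed genes called hypervariable, grouped as heat-shock, immediate-early, and globin and immunoglobulin genes, and each symbol is 1 of the 4 libraries. The 5 heat-shock genes are highest in replicate 3, and 7 immediate-early genes are highest in replicate 4.

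Of the 20 hypervariable genes with the smallest adjusted p, most share sequence with another gene. They are mt-Co2, the snRNA gene Gm24497, Hspa1b, Hspa1a, Gm10222, Gm10163, Zc3h11a, Rnu3a, Galnt2, mt-Co3, mt-Nd4l, Slc15a2, Gm10240, Gm13370, Rps12l1, Gm10443, Hsph1, mt-Atp6, Pagr1a and Egr1. The mitochondrial gene mt-Co2 (chromosome M, 7013 to 7696) went from 337 CPM in replicate 1 to 2.42 in replicate 4 (adjusted p = 3.9e-08 in edgeR), and this value is uncertain because the nuclear gene Gm28661 covers it at near identity. Slc15a2, a peptide transporter gene with no such copy, stood at 43.96 CPM in replicate 1 and at most 15.8 in the others (edgeR adjusted p = 0.00013), and its call was lost without replicate 1 (adjusted p = 0.29). Among the other genes of these 20, calls were also lost for Rps12l1 and mt-Atp6 without replicate 1, for Galnt2, Gm10240, Gm13370 and Gm10443 without replicate 2, for Hsph1 without replicate 3 and for Pagr1a without replicate 4. Among those tested with the read-based quantification, Zc3h11a, Galnt2 and mt-Atp6 lost their calls. With spike-in scaling, mt-Co3, Hsph1, mt-Atp6 and Egr1 did.

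Libraries differed little in the share of protein-coding genes and more in that of small nuclear and nucleolar RNA genes. Protein-coding genes held 68.6% ± 0.410 of the expected counts and 35.7% of the TPM, since short structural RNAs weigh more per count in TPM. The signal recognition particle RNA genes Rn7s1 and Rn7s2 held 5.59% ± 0.241 of the counts, Rn7sk 1.67% ± 0.0840, mitochondrial genes 7.52% ± 0.404, immunoglobulin genes 0.741% ± 0.0196, ribosomal protein genes 2.72% ± 0.0596, replication-dependent histone genes 0.188% ± 0.00868 and spike-ins 0.286% ± 0.0350. From replicate 1 to replicate 4, snRNA genes went from 0.681% to 0.480% of the counts (9.23% to 6.86% of the TPM) and snoRNA genes from 0.321% to 0.242% of the counts, with replicates 2 and 3 in between. Of the structural RNA list 8 of 10 genes were present, with Rpph1 at 14984 ± 238 and Rmrp at 10353 ± 397 TPM. Across genes, Pearson's r of log2(TPM+1) was 0.991 to 0.992 and Spearman's rho 0.923 to 0.925 for the 6 pairs of libraries, where genes are not independent replicates. No pair agreed within counting noise as 2 deposits of 1 library would, with a chi-square of 3.82 to 7.27 per degree of freedom, so each library was counted once. Between the alignment-based and the read-based quantification, r was 0.932 to 0.934 for all genes and 0.985 to 0.986 for protein-coding genes.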

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

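Of 134 sets of 4 values, 8 had a library farther from the others than Dixon's limit. Chance alone would give about 6.7 in sets not chosen for their spread. The sets include genes named because they were hypervariable, such as Rps12l1 and Pagr1a, and overlapping lists and shares, so 6.7 is only a rough guide. Of the tests below, those of spike-in scaling and of sequence sharing by hypervariable genes outside the lists were set before their results were seen, and those of summed heat-shock families, of a single scaling factor and of a response shared with the immediate-early genes after.

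In replicate 3, the median log2(TPM+1) of the innate list was 3.12 against a mean of 3.39 in the others, and Ighg2c made up 0.421% of heavy-chain constant TPM against 0.0936%. In replicate 1, the median of the neutrophil list was 0.299 against 0.429, the log2 ratio of Fcer2a to Cd1d1 was 2.42 against 2.86, and Rps12l1, which has near-identical copies, was at 42.3 TPM against 156. In replicate 4, Rn7s1 and Rn7s2 held 5.23% of counts against 5.71%, Pagr1a was at 15.6 TPM against 4.25 (its sum with Gm42742, which shares its sequence, was 20.3, 17.1, 16.7 and 20.7 CPM in replicates 1 to 4, adjusted p = 0.991 in edgeR), and Fau was at 1243 TPM against 1118. Signal also appeared in rows no comparison used: phiX174, a sequencing control, had 72, 40, 56 and 39 counts in replicates 1 to 4, and the tRNA rows had 8.72, 8, 10 and 3 counts.

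Heat-shock genes differed between libraries: all 11 tested members were highest in replicate 3 under TMM scaling. Reads divided between near-identical genes do not account for it, since all 7 families of the members with such copies were highest there once each was summed, by 0.274 to 1.81 on the log2 scale over the mean of the others (the listed genes held 77.7% or more of each sum), and one scaling factor for the whole library does not either, since the list's median log2 ratio of 0.55 to the other libraries lay above 100% of 10000 random lists. With spike-ins as library sizes 6 of the 11 were highest in replicate 3 and 5 in replicate 1, which lies between the limits set beforehand for that test, but this scaling shifts every gene of a library alike (0.23 in replicate 1 and -0.21 in replicate 3), so the count decides nothing about these genes. A response shared with the immediate-early genes also stays open. The median log2 ratio of those genes in replicate 3 to the others, 0.093 with TMM, lay above 99.6% of random lists. However, 15 of the 18 were highest in replicate 4 (13 with spike-in scaling). The heat-shock median there, -0.16, lay above 0.45% of random lists. It cannot decide the question, because the mean of the others includes replicate 3, which lowers this ratio. With TMM, the 5 called heat-shock genes were second highest in replicate 4 and lowest in replicate 1, while 5 of the 11 were lowest in replicate 4. No other biological explanation was tested, because the labels give no difference between the replicates.

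Most hypervariable genes outside the fixed lists may owe their spread to reads shared with another gene. Of these 47 genes, 40 (85.1%) share near-identical or overlapping sequence with another annotated gene, against 11.2% of 983 random tested genes (one-sided Fisher's exact p = 6.7e-29). This test treats genes as independent, although some of the 40 are copies of each other. The random genes were drawn from tested genes that were not hypervariable and were not matched for gene type. After counts were summed over each of the 29 families, which hold 41 of the genes, 6 (20.7%) were still past the threshold. However, a sum led by a far more abundant member would also dilute a true change in a minor one. Besides Mid1 and Xlr3b, the 6 were the families of Gm23238 and Gm24305, Gm23444, Gm23472 and Gm24497, Gm24265 and Gm24407, and Rnu3b1 to Rnu3b4. Except for Mid1 and Xlr3b, these sums were highest in replicate 1 and lowest in replicate 4, as were the shares of snRNA and snoRNA genes. Reads divided within these 6 families do not account for the spread of their sums. The sum of mt-Co2 and Gm28661 was 1895, 1897, 1890 and 1636 CPM in replicates 1 to 4 (adjusted p = 0.74 in edgeR). The 7 unshared genes outside the lists were named after their values were seen. Slc15a2, Lars2, Gm43305, Rbm15b, Eps8l1 and Gm24119 kept their calls in this refit, where no other gene was summed with them. The refit therefore did not test these calls. Each of them was lost with 1 replicate or another left out. With the read-based quantification, those of Gm43305 (adjusted p = 0.20 in edgeR) and Gm24119 (0.99) were lost as well. A Zc3h11a gene that is itself a partner of another gene of that name lost its call once summed with it (adjusted p = 0.991 in edgeR). Calls were kept by all 15 genes or families with a listed member. Of these, only Dnaja1, Hspa1a with Hspa1b, and Hba-a1 with Hba-a2 were sums of several genes.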

How the results depend on the processing

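No paired analysis was possible because there is 1 group, so that no samples pair between groups. Of 695 recomputed values, 645 of those chosen before and 3 of those chosen after seeing the data kept their direction, for differences and ratios whatever their size, stayed within the spread between replicates, for shares, or between the values without each replicate, for the coefficient of variation, or stayed within 1.5 times, for numbers of genes. With CPM, the log2 difference of the identity list from MHC class II genes went from -0.01 to 0.87 and from light-chain genes from -1.68 to 1.14, Cxcr4 against S1pr1 from 0.69 to -0.31 and H2-Ab1 against H2-Aa from 0.19 to -0.43; this unit does not correct for length. With list means, the differences were 9.6e-05 for MHC class II, -0.12 for follicular and -0.38 for structural RNA genes, which was -2.21 with members above 0.1 TPM. The follicular difference was -0.32 with the read-based quantification. Without each replicate in turn, the MHC class II difference ranged from -0.0517 to 0.0252. The coefficient of variation was 7.10% with no filter, 15.0% with spike-in sizes, 8.75% as the median over genes in DESeq2 (6.95% as the median over genes in edgeR) and 5.14% for protein-coding genes. Hypervariable genes numbered 244 with no filter, 0 with a robust prior, which treats such genes as outliers, and 37 to 49 without each replicate in turn. Once each hypervariable gene was summed with its near-identical partners, 41 genes or families were called. Near-identical genes with no hypervariable member were left unsummed. With the read-based quantification 79 were called, of which 33 were shared, including all 17 listed genes. A mean count of at least 50 left 13 of these 17. With expected counts, Ighm held 75.9%, Ighd 23.1% and lambda 37.9%. The read-based quantification gave 38.6% lambda and 35.8% for Ptprc-207 of all Ptprc. In TPM, protein-coding genes held 35.7%, mitochondrial genes 6.30%, immunoglobulin genes 1.09% and spike-ins 0.379%. In the same unit Rn7s1 and Rn7s2 held 27.4%, Rn7sk 7.09%, ribosomal protein genes 5.16% and replication-dependent histone genes 0.276%. Genes labelled lincRNA held 5.25% of the TPM, Gm26917 and Gm42418 4.16% and Malat1 0.592%. Other causes were not tested. Depth limits statements on genes near 3 counts.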

Other observations

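A pair of neighbouring genes held most counts of the genes that the annotation labels lincRNA. That label is the annotation's, and it was not tested which RNA these reads came from. Gm26917 (chromosome 17, 39843013 to 39846341) and Gm42418 (39846958 to 39848788) held 10.2% ± 0.370 of the expected counts, out of 12.5% ± 0.357 for all lincRNA genes. Malat1, a nuclear noncoding RNA, held 1.91% ± 0.0287. Of the 96 spike-in sequences, 51 to 59 had at least 1 count, and the 30 with a mean of at least 20 counts had a median coefficient of variation of 7.49% between libraries. The spike-in share was lowest in replicate 1 at 0.242% and highest in replicate 3 at 0.326%, and spike-in scaling moved all genes by 0.23, -0.05, -0.21 and 0.02 on the log2 scale in replicates 1 to 4.

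The tests on lambda chains were chosen after the counts were seen. Lambda light chains had fewer variable-region reads per constant-region read than kappa. Alignment-based counts gave 869 ± 46.0 on the 3 variable genes Iglv1, Iglv2 and Iglv3 and 11050 ± 242 on the constant genes, a ratio of 0.0786 ± 0.00294, against 0.531 ± 0.0146 for kappa. The heavy chains, whose constant regions are longer, had a ratio of 0.0946 ± 0.00194 in these counts, closer to lambda than to kappa. The heavy and lambda ratios were 0.0653 ± 0.00285 and 0.0656 ± 0.00144 in the read-based counts, and 0.560 ± 0.0122 and 0.106 ± 0.00379 in TPM. The gap to kappa remained in the read-based counts, where the lambda ratio was 0.187 of the kappa ratio. Both quantifications rest on the same reads, so this cannot exclude a loss of variable-region reads common to both. Length does not account for the gap, since the lambda ratio was 0.125 of the kappa ratio in TPM. Variable genes or alleles of the CAST/EiJ chromosome that differ from the C57BL/6 reference may be missed, but the ratio of 0.0786 cannot tell this from constant-region transcripts without a variable region, because reads and a CAST/EiJ sequence were not used here.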
